A study of Mus musculus with 14 samples.

How the data were processed

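Double-negative 3 (DN3) T-cell progenitors were sorted from the thymus of C57BL/6 mice with an Arid1a wild type (WT) or knockout (KO) genotype, per the labels. The titles of the KO libraries name Cre, and those of the WT libraries name a control without saying whether it carried Cre. An effect of Cre could therefore not be told apart from that of the knockout. RNA was sequenced in 3 WT and 3 KO libraries, and chromatin accessibility was measured by ATAC-seq in 1 library per genotype. CUT&RUN, which maps where an antibody's target sits on chromatin, was run with antibodies against ARID1A, TCF1 and IgG in the Scid.adh.2C2 pro-T tumour line, with 2 libraries per antibody. Groups followed the genotype and antibody labels.

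The deposited RNA file held raw read counts per gene, summed over exons with 1 transcript kept per gene on mm10, per the file headers. The submitters' processing notes name STAR 2.6.0b-1, HOMER 4.8, Bowtie2 2.3.4.2 and DESeq2 for the RNA and ATAC libraries, and Bowtie2 2.3.5, SAMtools 1.9, Trim Galore, Picard and MACS2 for CUT&RUN, with no role given to any of them. The mm10 assembly is also called GRCm38. The deposited ATAC signal was given as tags per peak scaled to 10000000 tags per library, per the file headers, over a merged set of DN3 and DN4 peaks that the authors built from another series. Multiplying each signal by its library's total gave whole reads within 0.02 for 100% of values, so reads were recovered. The deposited CUT&RUN files listed 1 set of peaks per antibody with a score, a fold enrichment ratio and −log10 p and q values in the layout of a peak caller. Whether the 2 libraries of an antibody were pooled, and whether IgG served as the control, is not given in the sources used here. No IgG peak list was used here.

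Genes with enough counts were kept by edgeR's filterByExpr. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test, two-sided, with genotype as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. Values per library are CPM, counts scaled to library sizes adjusted by TMM. The labels do not state that the 3 libraries of a genotype come from separate animals, so p-values measure the spread between these libraries.

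The tests, the alternatives, the naming rule and 26 gene lists were fixed before the data were examined. Arid1a was named first. The rule then named the 14 called genes with the largest rise and the 14 with the largest fall among genes with a mean log2 CPM of at least 1 and no overlap between the genotypes, and up to 4 members of each list with the smallest p. For ATAC it named the 5 highest and 5 lowest ratios among peaks with a mean of at least 50, and the strongest peak annotated to each named gene. For CUT&RUN it named the 5 peaks of each list with the highest score and the peaks nearest to named genes.

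Lists were tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 25 lists with at least 5 tested members. They covered BAF complex subunits, T-lineage transcription factors, early progenitor genes, DN3 identity and pre-TCR genes, Notch targets, post-beta-selection genes, gamma-delta T genes, NK and innate lymphoid genes, B-cell, myeloid, dendritic, erythroid, thymic stroma and mature T-cell genes, S phase and G2/M genes, p53 targets, the BCL2 family, interferon-stimulated genes, immediate early and heat shock genes, MYC and ribosome biogenesis genes, cytosolic ribosomal proteins, oxidative phosphorylation, cytokine and chemokine receptors, DNA repair and recombination, and transcripts of the mitochondrial genome. The RNA table held 0 of the 13 members of the mitochondrial list, so that list was not tested.

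ATAC signals were scaled to equal totals over peaks and compared as a log2 ratio of KO over WT with a pseudocount of 1, among peaks with a mean of at least 20. With 1 library per genotype no test across genes or peaks was possible, and ratios compare 2 libraries, not genotypes. The median of a group of peaks was set against 10000 random groups of the same size matched on mean signal in 20 bins. Intervals of named peaks are exact conditional binomial intervals at 95%, and they cover counting error only. The peak's gene and annotation are those of the deposited table, and CUT&RUN peaks were placed by the transcripts of the deposited RNA table. Peaks counted as overlapping at 1 shared base or more. The overlap of both antibodies and the RNA calls near bound peaks were compared by two-sided Fisher's exact tests, the latter over genes tested in RNA with at least 1 annotated ATAC peak and adjusted over 6 tests, also within 3 bins of mean expression.

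Alternatives fixed beforehand covered scaling, the filter on low counts, DESeq2 and limma-voom, a block for the replicate number, transcript length, stricter thresholds, leaving out each library, estimated correlation and fry for the lists, ATAC scaling, minimum, pseudocount and fold, and stricter definitions of a CUT&RUN overlap. After the data were seen, 7 were added: leaving out Rn45s, a sex term for genes and for lists, leaving out the libraries with Y-linked counts, a Mantel-Haenszel test over strata of the number of ATAC peaks per gene, distal peaks alone for the bound peaks, and an exact binomial test of the recovered reads. Motif searches at CUT&RUN summits were planned but not run, because no genome sequence was used here.

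On simulated counts from the means and depths of these libraries, over 12599 genes, the RNA test recovered 12.1% of genes changed 1.5-fold, 39.4% of those changed 2-fold and 78.5% of those changed 4-fold, with 1 false call. In simulated lists over 12584 genes, a list raised 1.5-fold was called and 0 of 20 unchanged lists were. Simulated genes varied independently, whereas the estimated correlation in the S phase list was 0.36. The simulation could therefore not show how often lists of correlated genes are called falsely. The matched random groups placed 7 of 100 simulated groups without effect outside the middle 95%, and a group lowered by 0.3 on the log2 scale at percentile 0, over 4000 simulated peaks.

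Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.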

Results

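RNA-seq libraries held 27976173, 23232620 and 28542682 counts in WT replicates 1 to 3 and 27892163, 26693616 and 17772326 in KO replicates 1 to 3. The ribosomal precursor gene Rn45s took between 20.9% and 25.7% of the counts of each library. Of 24072 genes, 12832 had enough counts to be tested. The ATAC libraries held 28636121 WT and 22904228 KO tags, of which 10.8% of WT tags (95% exact binomial interval 10.8% to 10.8%) and 14.2% of KO tags (14.2% to 14.2%) lay in 37198 peaks. The CUT&RUN lists held 6937 ARID1A and 6200 TCF1 peaks.

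Arid1a, the targeted gene (chr4:133679008-133753611, mm10/GRCm38, minus strand), stood at 897, 913 and 908 CPM in the WT libraries and at 669, 841 and 773 CPM in the KO libraries. All 3 KO libraries lay below all 3 WT libraries, at a log2 fold change of -0.25 (SE 0.0911). The change was not called at an adjusted p of 0.0936 by edgeR's quasi-likelihood test. The Arid1a log2 fold change was called lower by limma-voom (-0.26, adjusted p = 0.0326) and with length correction (-0.32, adjusted p = 0.0216). Counts cover the whole transcript and not the deleted part alone, so they check the labels only in part. The paralogue Arid1b rose from 85.5 to 157 CPM (log2 fold change 0.87, adjusted p = 3.43e-04).

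The first comparison asked which genes differ between Arid1a WT and KO DN3 cells. Lmcd1, a gene of LIM and cysteine-rich domains, rose from 5 counts over the WT libraries to 1096 over the KO libraries, a ratio of 252 (95% counting interval 108 to 777, which covers counting error only). Maf rose from 6.81 ± 1.30 to 92.6 ± 24.8 CPM (SD, n = 3 per genotype), and Ahnak from 3.31 ± 3.09 to 102 ± 25.7 CPM. The trafficking genes S1pr1 and Klf2 also rose, S1pr1 from 0.302 to 6.98 CPM and Klf2 from 0.655 to 9.15 CPM. Gng4, Syndig1l, Synpo2, Mc5r and Lrrc32 rose with log2 fold changes of 6.40, 6.01, 5.44, 4.57 and 4.06. The log2 fold changes of Lmcd1, Maf, Ahnak, S1pr1 and Klf2 were 7.89, 3.76, 4.94, 4.52 and 3.78, with adjusted p-values of 3.16e-05, 1.44e-06, 4.85e-05, 0.00617 and 8.26e-04. Without WT replicate 1 the log2 fold changes of Lmcd1, Gng4, Syndig1l and Mc5r were 11.57, 11, 7.64 and 3.99. Without WT replicate 3 those of Synpo2, Ahnak, Mc5r, S1pr1 and Lrrc32 were 6.10, 6.07, 7.89, 3.93 and 4.92, and without KO replicate 3 that of Syndig1l was 5.40. Maf and Klf2 moved by less than 1.5-fold without any 1 library. Tenm4, Prrg2, Gm15663 and Upb1 were called as well, at 4.23, 4.16, 3.94 and 3.78, but each lost its call when 1 library was left out, and Tenm4 also by limma-voom. The adjusted p then reached 0.129 for Tenm4 (lost without WT replicate 1 or 3, or KO replicate 1 or 2), 0.0986 for Prrg2 (WT 3, KO 1 or 3), 0.0693 for Gm15663 (KO 2) and 0.166 for Upb1 (any library but WT 2). Their log2 fold changes ranged from 3.41 to 4.8, 3.55 to 6.69, 3.39 to 4.61 and 3.19 to 6.16 when 1 library was left out. Gm15663 and the promoter of another transcript lie in the same interval, and the strand used in counting is not given, so its reads could not be assigned with certainty.

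Among the falls, Itgae, the integrin chain CD103, dropped from 35.7 ± 8.34 to 0.586 ± 0.307 CPM (SD, n = 3 per genotype). Fam163b dropped from 154 ± 6.63 to 6.92 ± 2.87 CPM, and the transcription factor gene Spib from 61.9 ± 12.1 to 3.04 ± 2.16 CPM. Their log2 fold changes were -5.85, -4.45 and -4.32, with adjusted p-values of 2.82e-06, 1.03e-06 and 2.91e-05. Hspg2, Chrna9, Adamtsl2, Galnt3, Col15a1, Vwce, Rapgef4 and Efr3b fell at log2 fold changes of -5.63, -5.11, -5.08, -4.51, -4.48, -4.37, -4.36 and -4.31. Slc27a6, Spire2 and Nkd1 were called at -5.98, -5.73 and -5.56, but WT replicate 2 carried most of their counts. Without WT replicate 2 the adjusted p-values of Slc27a6, Spire2 and Nkd1 were 0.0848, 0.508 and 0.290. By limma-voom the calls of Slc27a6, Spire2 and Nkd1 were lost as well, at adjusted p-values up to 0.325. Spire2 also lost its call without KO replicate 1, 2 or 3, and Nkd1 without KO replicate 2 or 3. Leaving out 1 library moved the log2 fold changes of Slc27a6, Spire2 and Nkd1 between -7.49 and -4.39, -6.99 and -1.85, and -7.36 and -2.84. Without KO replicate 1 those of Hspg2, Chrna9, Adamtsl2, Rapgef4, Spib and Efr3b were -7.97, -6.22, -4.50, -5.26, -5.10 and -6.54. Without KO replicate 3 those of Adamtsl2 and Col15a1 were -6.74 and -5.83, without KO replicate 2 that of Vwce was -5.84, and without WT replicate 3 that of Rapgef4 was -3.73. Itgae, Fam163b and Galnt3 moved by less than 1.5-fold.

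Over all tested genes, 910 were called higher and 877 lower in KO (1787 genes, 13.9%), of which 370 and 456 changed at least 2-fold. At an unadjusted p below 0.05 there were 3351 genes. The genotypes did not overlap in 4062 genes (31.7%), where chance alone gives 10% for 3 against 3. Without WT replicate 1 there were 607 higher and 567 lower genes, and without WT replicate 3 there were 659 and 580. With library size as the only scaling, which moved the median of all genes to -0.06, 41.7% of calls were higher in KO, against 50.9% as reported.

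**Figure D1:**
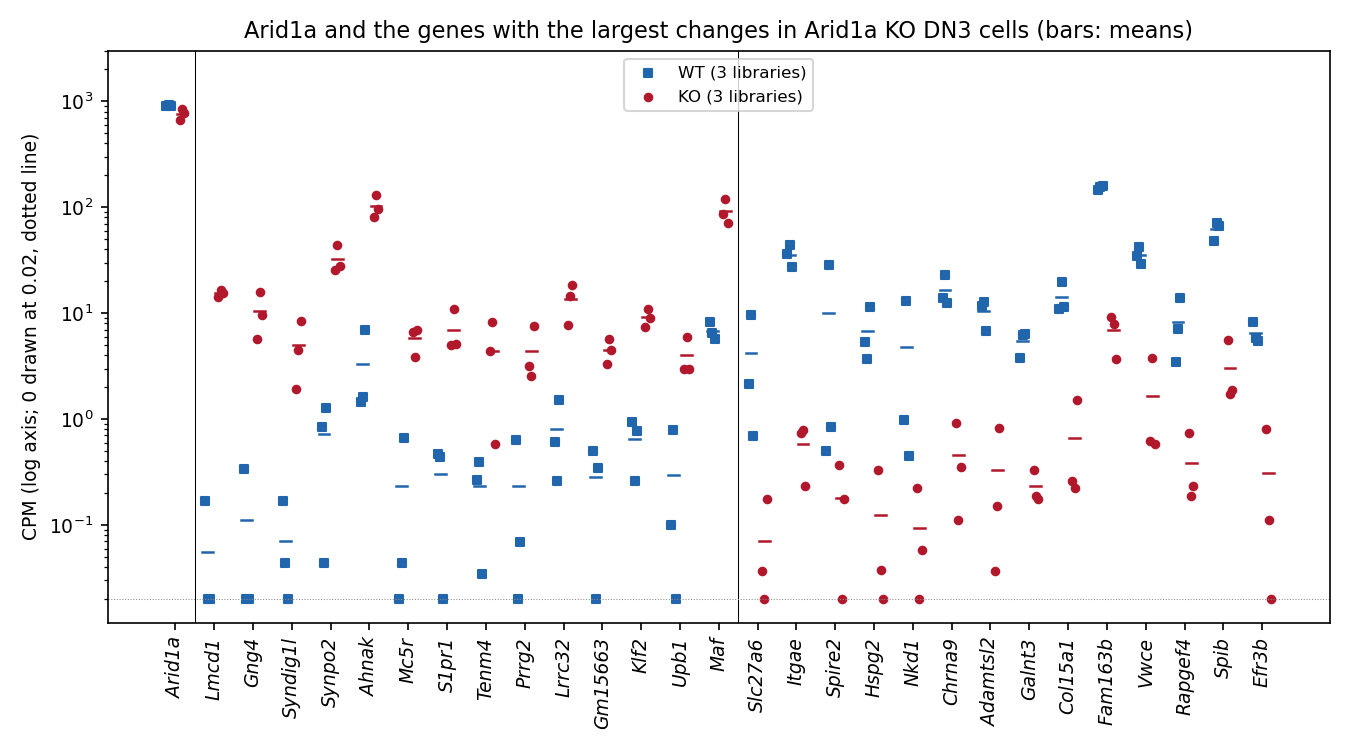
CPM of Arid1a and the 28 genes named by the rule in each of 3 WT (squares) and 3 KO (circles) libraries, on a log axis, with short bars at the means. The 14 genes that rose stand left of the second vertical line and the 14 that fell stand right of it.

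Interferon-stimulated genes stood higher in KO. Gbp7 rose from 170 to 436 CPM, Parp14 from 103 to 279, Stat1 from 229 to 482 and Gbp2 from 22.3 to 69.7, with log2 fold changes of 1.36, 1.44, 1.07 and 1.64. Of 40 members 25 were called higher and 1, Bst2 (-0.90), lower, and 30 and 1 when adjusted over the list alone, with a median of 1.11. The list's adjusted p was 1.44e-15 by camera, and the adjusted p = 0.233 with an estimated correlation. Without KO replicate 2, 18 members were called higher.

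Cell cycle genes stood lower. In S phase, Uhrf1 fell from 299 to 76.1 CPM, Rrm2 from 141 to 33.9, E2f8 from 75.7 to 15.1 and Ung from 88.8 to 31.9. In G2/M, Top2a fell from 560 to 191 CPM, Mki67 from 1409 to 507, Kif11 from 172 to 52.5 and Aurkb from 43.9 to 10.5. Of 36 S phase members 0 were called higher and 27 lower (0 and 31 adjusted over the list alone), with a median of -0.88. Of 45 G2/M members 1 was higher and 26 lower (1 and 32 adjusted over the list alone), with a median of -1.03. The adjusted p-values were 2.51e-17 and 2.58e-14 by camera, and adjusted p = 0.249 with an estimated correlation for S phase and adjusted p = 0.156 with an estimated correlation for G2/M.

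Of the growth genes, Hspd1 fell from 230 to 96.7 CPM, Srm from 116 to 54.0, Cad from 122 to 74.2 and Nop2 from 71.8 to 34.0. Of 34 MYC and ribosome biogenesis genes 1 was called higher and 16 lower (1 and 19 adjusted over the list alone), with a median of -0.50. The adjusted p was 6.31e-07 by camera, and adjusted p = 0.340 with an estimated correlation. Between 7 (without WT replicate 3, KO replicate 1 or KO replicate 2) and 15 members were lower when 1 library was left out, and 10 without WT replicate 1. In oxidative phosphorylation and the cytosolic ribosomal proteins most members were not called, 45 of 49 and 55 of 57. Sdhb fell from 57.7 to 30.7 CPM, and of 49 oxidative phosphorylation genes 0 were called higher and 4 lower (0 and 4 adjusted over the list alone; median -0.25; camera adjusted p = 4.24e-04; adjusted p = 0.249 with an estimated correlation). Of those, Cox5a and Atp5g3 lost their calls without WT replicate 1, WT replicate 3 or KO replicate 2, at adjusted p-values up to 0.0620 and 0.0795, and Atp5a1 without any library but KO replicate 3, at up to 0.134. Of 57 ribosomal protein genes 2, Rplp1 and Rpl14, were called lower, and 0 were adjusted over the list alone (median -0.17; camera adjusted p = 0.00249; adjusted p = 0.370 with an estimated correlation). Rplp1 lost its call without each library in turn and Rpl14 without each but WT replicate 2, at up to 0.145 and 0.172. With length correction Rplp1, Rpl14 and Atp5g3 lost their calls.

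Of the mature T-cell genes, Sell rose from 372 to 724 CPM, Slamf6 from 70.5 to 146 and Ctla4 from 58.6 to 178, while Cd3e fell from 1954 to 1183. Of 14 members 8 were called higher and 1 lower (8 and 1 adjusted over the list alone), with a median of 1.00. The adjusted p was 0.00159 by camera, and adjusted p = 0.340 with an estimated correlation. Of the immediate early genes, Klf6, Zfp36 and Junb rose at log2 fold changes of 1.28, 2.61 and 1.61. Of 25 members 10 were called higher and 3 lower (10 and 4 adjusted over the list alone), with a median of 0.43. The adjusted p was 0.0248 by camera, and adjusted p = 0.249 with an estimated correlation. That call was lost without KO replicate 1 or KO replicate 3, where the adjusted p reached 0.0539, and also with a sex term, at a mean CPM of at least 5 and in a further alternative given in the closing section. Without WT replicate 3 or KO replicate 2, 0 members were called lower.

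Camera made these 8 list calls, 3 higher and 5 lower, with a preset correlation. None of the 8 held with an estimated correlation. Fry called all 8 in the same directions, at adjusted p-values from 0.00507 to 0.0331. Camera asks whether a list's genes shift relative to other genes, while fry asks whether they change at all. The fry calls therefore do not make up for the lost camera calls. Another split of the 6 libraries into 3 and 3, which mixed the genotypes, gave 7 called lists by the same test. The sides of that split still differed in their share of KO libraries, so it was not free of a genotype difference.

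**Figure D2:**
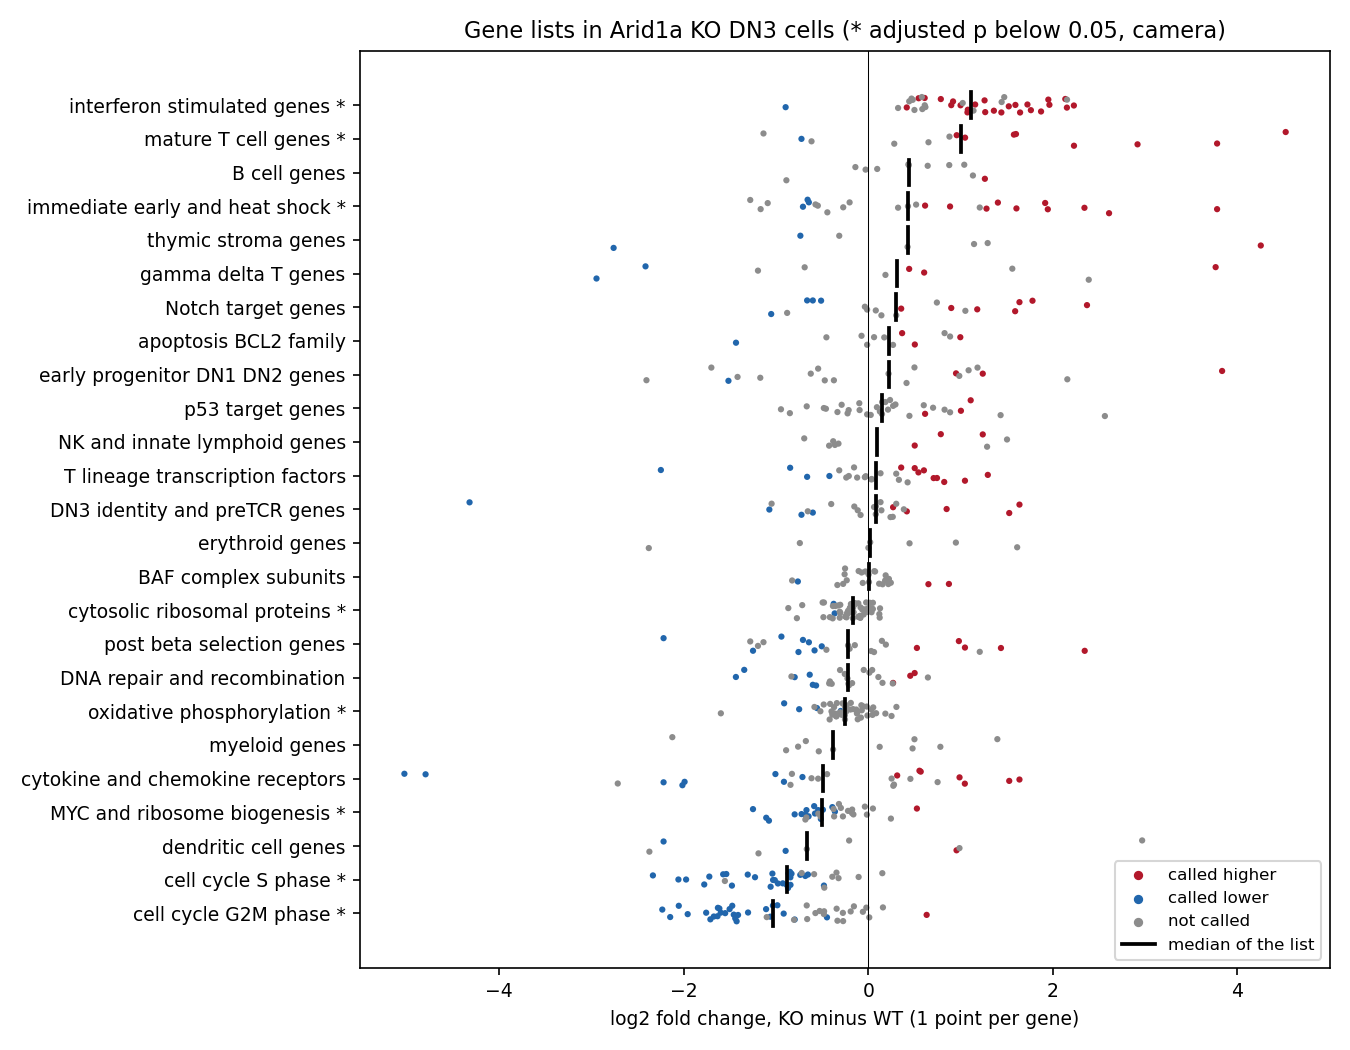
Log2 fold change (KO minus WT, x axis) of the tested members of 25 gene lists, with red points called higher, blue points called lower and grey points not called. Black marks are medians, from -1.03 in G2/M to 1.11 in interferon-stimulated genes, and a star marks lists with an adjusted p below 0.05 by camera.

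The lineage lists moved in both directions. Il2ra, which encodes CD25, rose from 2330 to 7253 CPM and Il7r from 166 to 478, while Rag1 fell from 1892 to 1248 and Spib fell as above. Tcf7, the gene of TCF1, fell from 2178 to 1376 CPM, and Myb, Runx3 and Fli1 rose at log2 fold changes of 0.71, 1.30 and 0.82. Among Notch targets Uaca and Dtx1 rose at 2.37 and 1.78. Ccr9 fell from 331 to 70.9 CPM. None of these lists was called by camera, while fry called the T-lineage transcription factors and Notch targets higher (adjusted p = 0.00963 and 0.0102) and the post-beta-selection genes lower (0.0354). Called higher and lower were 5 and 4 of 24 DN3 identity and pre-TCR genes (9 and 5 adjusted over the list alone; adjusted p = 0.702), 9 and 4 of 26 T-lineage transcription factors (10 and 5; 0.171), 7 and 4 of 19 Notch targets (8 and 4; 0.134), 5 and 8 of 25 post-beta-selection genes (5 and 9; 0.170) and 7 and 8 of 26 cytokine and chemokine receptors (7 and 9; 0.553). Without KO replicate 1 the post-beta-selection list was called lower, at an adjusted p of 0.0351. Without WT replicate 1 its members called higher and lower numbered 1 and 5, and without WT replicate 2 or KO replicate 2 there were 3 higher. Without WT replicate 1, WT replicate 3 or KO replicate 2, 3 DN3 identity genes were called higher.

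The BAF, p53, BCL2 and DNA repair lists were not called by camera, while fry called the BCL2 family higher (adjusted p = 0.0155). Smarcd2, a BAF subunit, fell from 131 to 77.1 CPM while Bcl7a rose from 87.5 to 137, and Cdkn1a, a p53 target, rose from 101 to 218. Bmf rose and Bid fell, at log2 fold changes of 1.00 and -1.43. Brca1 and Rad51 fell at -1.34 and -1.43. Called higher and lower were 2 and 1 of 24 BAF complex subunits (2 and 1 adjusted over the list alone; camera adjusted p = 0.888), 3 and 0 of 32 p53 targets (3 and 0; 0.119), 3 and 1 of 12 BCL2 family genes (3 and 1; 0.211) and 3 and 6 of 26 DNA repair genes (4 and 9; 0.118).

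Markers of other lineages gave no called list by camera, while fry called the B-cell genes higher and the stroma genes lower (adjusted p = 0.0212 for both). The 7 stroma genes had a median log2 fold change of 0.43, with 4 above 0 and 3 below, and camera's direction for them was higher. The stroma list thus had no clear direction. Id2 and Nkg7 rose at log2 fold changes of 1.24 and 0.79, Cd163l1 fell at -2.94, and Epcam fell at -2.76. Nkg7 lost its call when the libraries with Y-linked counts were left out. Called higher and lower were 3 and 1 of 19 early progenitor genes (4 and 4 adjusted over the list alone; camera adjusted p = 0.888), 3 and 2 of 10 gamma-delta genes (3 and 3; 0.702), 3 and 0 of 10 NK and innate lymphoid genes (4 and 0; 0.358), 1 and 0 of 11 B-cell genes (1 and 0; 0.154), 0 and 0 of 11 myeloid genes (0 and 0; 0.904), 1 and 2 of 9 dendritic genes (2 and 2; 0.442), 0 and 0 of 7 erythroid genes (0 and 0; 0.888) and 1 and 2 of 7 stroma genes (2 and 2; 0.888). The single B-cell call, Cd74, was lost without any library but WT replicate 1, at adjusted p-values up to 0.0768. Of the early progenitor calls, Nfe2, Hoxa7 and Lmo2 were lost without KO replicate 2 and other single libraries (up to 0.111, 0.173 and 0.316), as were Psmb11 and Pdgfrb of the stroma list without WT replicate 1 and others (up to 0.0826 and 0.147). By limma-voom Lmo2 and Psmb11 lost theirs as well.

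The second comparison set chromatin accessibility in KO against WT, with 1 library each and no test. Promoter peaks had a median log2 ratio of KO over WT of 0.27 over 6966 peaks. That of Vwa9 (chr9:64960537-64961221) stood far above this median, at 1.23. Intron and intergenic peaks had medians of -0.22 over 4631 peaks and -0.21 over 3754 peaks. One in intron 5 of Magi2 (chr5:20299778-20300671) stood far below them, at -2.19. The promoter median exceeded that of intron and intergenic peaks together by 0.48. Across 10 bins of signal that gap ranged from 0.56 to 0.08, the latter in the bin with the highest signal. Intron and intergenic peaks together had medians of 0.10, 0.15 and 0.23 in the 3 bins with the highest signal, and 0.10 at a minimum signal of 50, so their sign turned with the signal. Of 17658 peaks, 45 were at least 2-fold higher and 1464 at least 2-fold lower in KO, so that 97.0% of them were lower, although the median of all peaks was 0.10 and 58.4% of peaks lay above 0. At 1.5-fold there were 1172 higher and 2925 lower peaks. The peak set was built from another series and not from these libraries. Sites open only in KO could therefore be missing from these counts. As deposited, without scaling to equal totals, 995 were higher and 593 lower (37.3%), and the medians of promoter and of intron and intergenic peaks were 0.66 and 0.21, both above 0. With the median of the strongest peaks set to 0 those medians were -0.00 and -0.50. The sign of either group thus rested on the scaling, and the gap remained, at 0.46 and 0.50.

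**Figure D3:**
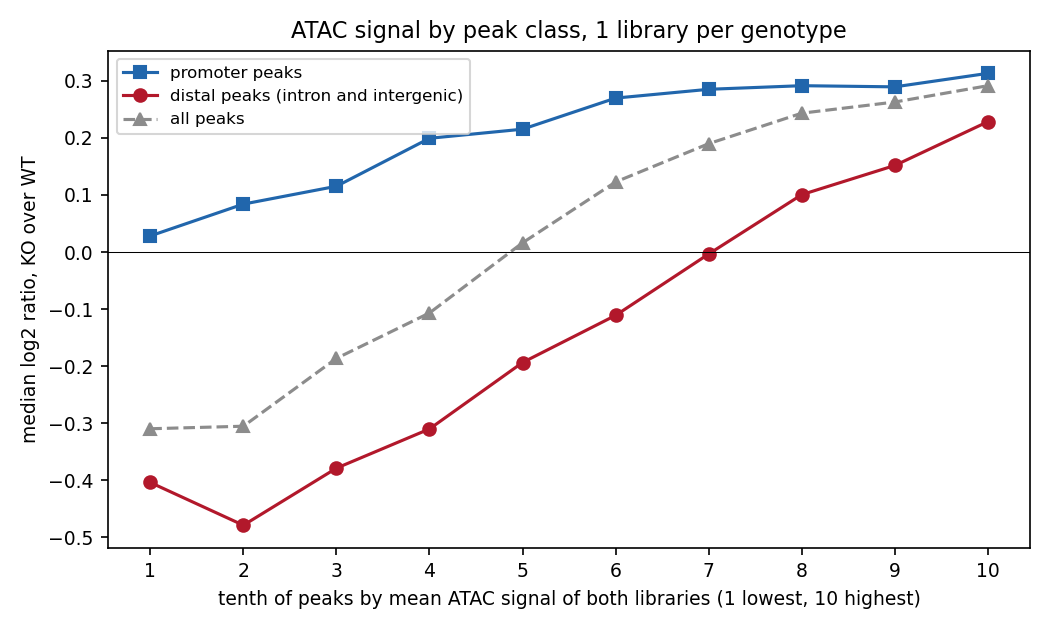
Median log2 ATAC ratio (KO over WT, y axis) of promoter peaks, of intron and intergenic peaks and of all peaks in 10 bins of 17658 peaks ordered by mean signal (x axis). Promoter peaks lie above distal peaks in each bin, by 0.43 in the lowest and 0.08 in the highest.

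The lowest ratios named by the rule lay at an intergenic peak nearest to Vapb (chr2:173854843-173855730, mm10/GRCm38; 39 KO and 213 WT reads), in intron 24 of 34 of a Cacna1g transcript in a peak assigned to Abcc3 (chr11:94423974-94424965), at an intergenic peak nearest to Prg2 (chr2:84963856-84965034), in Magi2 and in intron 13 of Syne1 (chr10:5384058-5384742). The Vapb peak, 5.76-fold higher in WT (interval 4.08 to 8.33), overlapped both an ARID1A and a TCF1 peak. The highest ratios lay in intron 9 of Efhc1 (chr1:20986081-20987004), at the promoters of Vwa9 and Blm (chr7:80534973-80535564), and in intergenic peaks near Atg16l2 (chr7:101310374-101311039) and Gsk3a (chr7:25239233-25239582), from 2.19-fold at Blm to 2.47-fold at Efhc1 (interval 2.03 to 3.01). Among genes that fell in RNA, the strongest peak of Nkd1, in intron 1 (chr8:88530949-88531832), held 33 KO and 167 WT reads and was 5.34-fold higher in WT (3.66 to 8.01). The Spib peak held 9 and 48 reads, below the minimum. Of genes that rose, Mc5r and Maf had peaks 1.66-fold and 1.30-fold higher in KO, while a Gng4 intron peak was 2.39-fold higher in WT. The Maf peak, the strongest of 17 assigned to that gene, lay 516844 bp from its TSS in intron 8 of another transcript. ATAC peaks that overlapped the ARID1A peaks nearest to Maf had log2 ratios from -1.31 to 0.18. Of the 14 rises, 9 had a peak past the minimum, 3 above 0 and 6 below, and of the 14 falls 10 had one, 3 above 0 and 7 below. As deposited the rises split into 8 above and 1 below, Gng4, and the falls into 5 and 5, so this tally turned with the scaling. Prrg2 had no annotated peak.

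Peaks of genes that fell in RNA were lower in ATAC than matched peaks. Their median log2 ratio was -0.02 over 1180 peaks of 708 genes, against 0.12 in 10000 matched random groups, at percentile 0 of those groups. The gap of -0.14 shrank to -0.041 at a minimum signal of 50 and to -0.081 for peaks within 10 kb of a TSS, and was -0.29 for genes changed at least 2-fold. Peaks of genes that rose had a median of 0.11 over 1621 peaks of 762 genes, at percentile 41.1. Among peaks over 1 kb from a TSS the medians were -0.51 against -0.29 for falls (percentile 0) and -0.10 against -0.25 for rises (percentile 100). As deposited, the medians over all peaks of falls and rises were 0.40 and 0.52, so the gap to matched peaks and not the sign is reported.

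The third comparison asked where ARID1A and TCF1 sit together in the pro-T line. The ARID1A peak with the highest score lay in Nck2 (chr1:43465101-43465284, score 259), followed by peaks in Hs6st3, Ms4a4d and Cd226 and one near Fabp7. The highest TCF1 score lay near Pde4dip (chr3:97734318-97734455, score 315), followed by peaks in or near Arhgef10l, Fra10ac1, Nipa2 and Mboat4. Within 1 kb of a TSS lay 6.99% of ARID1A and 7.85% of TCF1 peaks. Of ARID1A peaks 2552 (36.8%) overlapped a TCF1 peak, and of TCF1 peaks 2556 (41.2%) overlapped an ARID1A peak. An ATAC peak was overlapped by 46.0% of ARID1A and 42.9% of TCF1 peaks. Comparisons made on ATAC peaks, here and below, leave out the other bound sites. Of ATAC peaks, 1274 held both, against 191 expected from independent lists, at an odds ratio of 22.0 (20 to 24.1). Peaks of both antibodies lay near Ahnak, Rapgef4, S1pr1, Klf2, Maf, Chrna9 and Spire2 among the named genes, and a TCF1 peak lay 3.15 kb from the Arid1a TSS. Signal shared by all antibodies, as IgG would show, could not be removed here.

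ATAC peaks that held both ARID1A and TCF1 peaks had lower ratios than matched peaks. The Vapb peak and one 307 kb from Maf stood far below the median of this group, at log2 ratios of -2.45 and -1.31. The median log2 ratio of co-bound peaks was -0.40 over 716 peaks, against 0.03 in matched random groups. Of those 716 peaks, 21.4% were at least 2-fold lower, against 7.19% of 15288 peaks with neither. As deposited those shares were 8.79% and 3.00%. Among peaks over 1 kb from a TSS, where promoters do not enter, the shares lay closer together. They were 24.1% with both, 23.5% with TCF1 alone, 16.4% with ARID1A alone and 17.1% with neither. Peaks with ARID1A alone had a median of 0.00 against 0.11 over 959 peaks, and peaks with TCF1 alone -0.05 against 0.11 over 695. All 3 lay at percentile 0 of the matched groups. At a minimum signal of 50, ARID1A alone lay at percentile 9.3, inside the middle 95%, TCF1 alone at 2.04 and co-bound peaks at 0, with gaps of -0.018, -0.036 and -0.19. The co-bound median was then 0.06, above 0. Promoters made up 9.08% of the co-bound peaks and 42.4% of those with neither. As deposited, the co-bound median was 0.02 against 0.44, so its sign turned with the scaling as well as with the minimum, and its gap to matched peaks did not. Among peaks over 1 kb from a TSS, co-bound peaks stood at -0.49 against -0.26 and TCF1 alone at -0.49 against -0.25 (both at percentile 0), and ARID1A alone at -0.31 against -0.26 (percentile 8.37). The CUT&RUN lists come from a cell line and the ATAC from sorted cells.

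**Figure D4:**
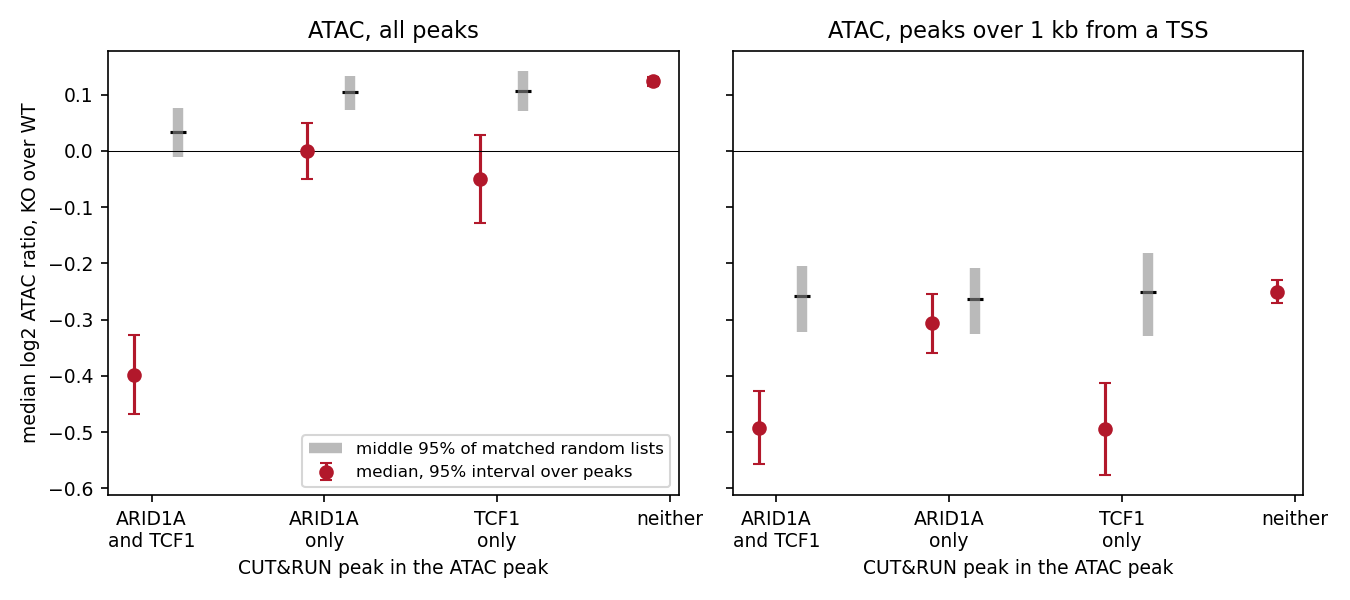
Median log2 ATAC ratio (KO over WT, y axis) of peaks that hold CUT&RUN peaks of both antibodies, of 1 or of neither, over all peaks (left) and over peaks more than 1 kb from a TSS (right), with 95% intervals over peaks. Grey bars are the middle 95% of matched random groups; co-bound peaks lie below them at -0.40 and -0.49 (and at 0.02 over all peaks as deposited).

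Genes that rose in KO had bound peaks more often than other genes. Klf2, Maf and Ahnak are among them, each with at least 1 ATAC peak that held both antibodies. Of 844 genes called higher, 27.5% had an ARID1A peak in an annotated ATAC peak, against 12.7% of other genes (odds ratio 2.6, adjusted p = 1.09e-26 by Fisher's exact test). The shares were 25% and 12.7% for TCF1 (odds ratio 2.28, adjusted p = 1.54e-19), and 15.8% and 6.38% for both in 1 peak (2.75, adjusted p = 5.48e-19). With calls limited to changes of at least 2-fold, the odds ratios of higher genes were 1.72, 1.99 and 2.17. Their adjusted p-values by Fisher's exact test were 2.83e-04, 5.53e-06 and 3.23e-05. For 784 genes called lower, among them Chrna9 and Rapgef4, the odds ratios were 1.24, 1.26 and 1.33, with adjusted p-values of 0.0363, 0.0351 and 0.0363. Genes with more ATAC peaks can carry more bound ones. Over strata of the number of peaks, the odds ratios of higher genes were 1.65, 1.46 and 1.58 (adjusted p-values of 1.62e-07, 9.81e-05 and 9.81e-05), and those of lower genes 1.03, 1.06 and 1.08, no longer called (0.813, 0.724 and 0.724). Split into 3 bins by mean expression, lower genes of the lowest bin were called for ARID1A and TCF1 (odds ratios 1.67 and 1.9, adjusted p-values 0.0412 and 0.0107), and higher genes of that bin were not (1.71 and 1.49, 0.0567 and 0.114). For both antibodies in 1 peak the lowest bin gave 2.03 for higher and 1.64 for lower genes (0.0412 and 0.0926). In the middle bin higher genes were called for ARID1A and TCF1 (1.74 and 2.04, 0.0241 and 0.00223), and lower genes for both in 1 peak (1.81, 0.0466). In the highest bin higher genes had odds ratios of 2.5, 2.23 and 2.63, all called, and lower genes 0.893, 0.990 and 0.921, none called.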

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

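The tests with Rn45s left out, a sex term, the libraries with Y-linked counts left out, the Mantel-Haenszel strata, distal peaks alone at bound peaks and the binomial test of reads were chosen only after the data were seen. No log2 fold change of a named gene reversed under the alternatives run. The direction of the ATAC results did turn with the scaling: 97.0% of peaks changed at least 2-fold were lower after scaling to equal totals, against 37.3% as deposited, 91.4% by TMM and 99.8% with the strongest peaks set to 0. At the first scaling the share was 71.4% at 1.5-fold.

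RNA genes changed in Arid1a KO (RNA genes higher in KO, RNA genes lower in KO) numbered 826 (370, 456) with a log2 fold change of at least 1 added and 861 (438 and 423) at an adjusted p below 0.01, since both narrow the same calls. Leaving out each library in turn gave 1174 to 1610 genes in all, 607 to 795 higher and 567 to 815 lower, with 1174 and 567 without WT replicate 1 and 580 lower without WT replicate 3. With the replicate number as a replicate block, 885 genes were higher and 866 lower, 1624 of them among the 1787, and of the named genes Spire2, Nkd1, Hoxa7, Lmo2 and Rpl14 were not called. Over all genes, libraries that share a number had deviations that hardly correlated (0.05, -0.00 and 0.06), although both libraries numbered 3 shared the Y-linked counts, so the unpaired test was reported. Of 101 called genes among the 120 named, 23 lost the call in at least 1 of 19 alternatives and 8 others gained one.

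Arid1a was called lower by limma-voom (-0.26), with length correction (-0.32) and with that correction and the block (-0.32), and it ranged from -0.32 to -0.16 when 1 library was left out. The cause was not tested.

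With an estimated correlation 0 lists were called higher and 0 lower, and fry called 7 higher and 7 lower. The call of the immediate early list was lost with the replicate block (adjusted p 0.109), at a mean CPM of at least 5, with the sex term and without KO replicate 1 or 3 (up to 0.0539).

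ATAC peaks changed at least 2-fold numbered 106 higher by TMM, 2505 (4 higher, 2501 lower) with the strongest peaks set to 0, 995 higher and 593 lower as deposited, 3816 (116 and 3700) at a minimum of 10, 125 (7 and 118) at a minimum of 50, 20 higher at a pseudocount of 5, 4097 (1172 and 2925) at 1.5-fold and 7052 (3780 and 3272) by the binomial test, which covers counting error between 2 libraries only and carries no conclusion. The KO library had the larger share of tags in peaks, and scaling to equal totals evens out only the sum over peaks. After that scaling the median log2 ratio still ran from -0.31 in the bin with the lowest signal to 0.29 in the highest. Whether the unequal share of tags in peaks underlies this was not tested. The promoter gap over distal peaks was 0.46 as deposited, 0.57 at a minimum of 10, 0.20 at 50 and 0.44 at a pseudocount of 5.

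Against matched peaks, those of genes lower in RNA stood at -0.041 at a minimum of 50, -0.081 within 10 kb, -0.22 at distal peaks and -0.29 for 2-fold changes, and those of higher genes at 0.15 at distal peaks. Co-bound peaks stood at -0.19 at a minimum of 50, -0.52 for the stricter lists and -0.23 at distal peaks. ARID1A alone stood at -0.16 (minimum 10), -0.018 (minimum 50), -0.20 (summits), -0.20 (stricter lists) and -0.044 (distal), and TCF1 alone at -0.29, -0.036, -0.39, -0.36 and -0.24. At a minimum of 50 and at distal peaks ARID1A alone lay inside the middle 95% of matched groups (percentiles 9.3 and 8.37). In the stricter lists 988 ARID1A peaks overlapped a TCF1 peak, since fewer peaks were compared. The cause of the other differences was not tested.

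The odds ratios of genes lower in RNA lost their calls with summits, stricter lists, 2-fold changes, peaks within 10 kb and strata: 1.29, 1.04, 1.24, 1.2 and 1.03 for ARID1A, 1.15, 1.16, 1.33, 1.28 and 1.06 for TCF1, and 1.28, 1.17, 1.39, 1.38 and 1.08 for both. The cause was not tested. The motif alternatives were not run, since no genome sequence was used here. Depth was lowest in KO replicate 3, with 17772326 counts, and without it 1610 RNA genes changed in Arid1a KO.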

Other observations

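The tests of the interferon and cell cycle patterns and the count of genes in other splits were chosen or reworded only after the result was seen. So was the set of MHC class I and antigen processing genes.

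The genotype split gave 1787 genes, 1 of 10 splits with a count as large, and the highest other split gave 0. It gave 8 lists, also 1 of 10 splits, and the highest other split gave 7. With 10 splits no share under 0.05 can be reached. The other splits mix the genotypes within each side, which widens the spread there, and leave a genotype difference between the sides. Their counts therefore do not show what libraries of equal genotype would give.

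Interferon-stimulated genes stood higher in KO. A single library is argued against, since at least 18 members were called higher without any 1 library. RNA from myeloid, dendritic, B or NK cells stays open: 35 of their markers rose by 43.8 CPM in sum, 2.91% of the interferon list's 1501 CPM, and all 41 fell by 114 CPM (-7.62%), but without Ccr9 the other 40 rose by 146 CPM (9.72%), with Cd74, Gata3, Id2, Ly6d and Nkg7 called higher. Of these, Gata3 is also on the T-lineage transcription factor list and rose from 175 to 248 CPM. The 146 CPM were therefore not from markers of other cells alone. Cd74 lost its call without any library but WT replicate 1, and 0 of 11 myeloid genes were called. RNA from mature T cells stays open too: 12 mature T genes rose by 242 CPM, 16.1% of the interferon list's rise, but 8 of 14 were called higher. Among genes chosen after their values were seen, Cd4 rose from 5.97 to 30.6 CPM. Of those genes Cd3e, Cd5, Cd27 and Cd28 were called lower, and Cd6 and Cd8a were not called. The sort removed cells positive for CD3, CD4, CD8 or lineage markers such as Mac1, CD19, NK1.1 and CD11c. A response to loss of Arid1a may also account for the interferon pattern.

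Cell cycle genes stood lower in KO. The S phase and G2/M medians stayed at or below -0.87 under 3 other scalings. Those scalings put the median of all genes between -0.06 and 0.00, against -0.00 as reported, so they hardly tested scaling. A scale per library moves all genes alike, and the lists, at -0.88 and -1.03 as reported, lay below the median of all genes. Without the library with the fewest counts the list medians were -0.91 and -0.97, so the fall did not rest on the depth of that library. A lower share of cells past beta-selection stays open: 8 of 25 post-beta-selection genes were called lower and 5 higher, and 5 and 1 without WT replicate 1, so that the balance rested in part on 1 library. Slower division in KO was not measured and may apply as well.

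ATAC peaks bound by ARID1A and TCF1 stood lower than matched peaks. The gap to peaks of the same signal was -0.43, but those peaks were not matched on their share of promoters. Among distal peaks of the same signal the gap was -0.23. A lower share of promoter peaks may therefore account for part of the gap. Neither signal nor promoter share alone accounts for the part left at distal peaks. At a minimum signal of 50 the gap over all peaks was -0.19. Peaks with TCF1 alone had a distal gap of -0.24, so the part left was not particular to co-bound peaks. A library difference unrelated to genotype cannot be told apart from genotype with 1 library per genotype.

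Replicate 3 of both genotypes held 166 and 66 Xist counts, against 210199 or more in the others, and 2865 and 1896 Ddx3y counts, against 1 or fewer. Peaks found in DN3 alone had a median log2 ATAC ratio of -0.33 and peaks found in DN4 alone 0.05, and 0.05 and 0.43 as deposited, so the sign of the former turned with the scaling. Promoters made up 14.3% and 35.3% of them. Of 25 lists examined, peaks of 3 lay outside the middle 95% of matched groups: cytokine receptors at percentile 0.4, oxidative phosphorylation at 99.6 and cytosolic ribosomal proteins at 99.99. Among promoter peaks alone those 3 lay at 47.5, 89.9 and 99.8, the NK and innate lymphoid list at 0.06 and the BAF list at 98.9. Of 18 genes of MHC class I and its antigen processing, a set chosen after its values were seen, 11 were called higher and 0 lower. The 18 were H2 genes together with B2m, Tap1, Tap2, Tapbp, Psmb8, Psmb9 and Nlrc5.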
